A study of Mus musculus with 9 samples.

How the data were processed

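Total RNA of 3 MEF, 3 CiCM and 3 CM samples was measured on 1-colour Affymetrix expression arrays, 1 array per sample, after amplification and biotin labelling with a 3' kit, per the labels' protocols. RNA was extracted with TRIzol, checked for integrity and purified on columns, per the labels' protocols. The deposited table holds log2 signals of 45101 probe sets on the 9 arrays; MAS5 is named per the submitters' processing notes, without a version. No label gives the scale of the table. The values ran like log2 values of MAS5 signals, and after 2 to the power of each value the mean without the highest and lowest 2% was 500.003 on every array, as global scaling leaves it. Medians of the deposited log2 values were 6.38, 6.37 and 6.53 for MEF replicates 1 to 3, 6.41, 6.53 and 6.52 for CiCM, and 6.78, 6.85 and 6.75 for CM. The group medians differed by 0.37 for CM minus MEF, -0.31 for CiCM minus CM and 0.06 for CiCM minus MEF. Scan dates, array batches, detection calls and single-probe signals were not analysed here, so a batch that follows the groups cannot be told apart from them.

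The design had been written for linear signals with 32 added before log2, with the deposited values to be used unchanged if they proved to be log2 values already. They did, so nothing was added, and 32, 1 and 128 added to the linear signals are alternatives. The use of 32 as an alternative to the deposited values, and a levelling of the arrays on their 18 hybridisation control probe sets, were chosen after seeing the data. The other alternatives, the tests, the tested gene lists and the rule for named genes were fixed before the data were examined. Lists of atrial, myoblast progenitor and Hox genes, used only in the closing section, were written afterwards.

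Probe sets were named through GEO's platform annotation, which can be old; 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were controls. No genome build is given in the sources used here, so no positions are printed. Symbols were compared with current RefSeq names through the Entrez identifier, and none needed an update. Each of 18194 genes was represented by its probe set with the highest mean over all 9 arrays, among those with exactly 1 symbol. Genes whose highest group mean was under 6.58, the median of the table, were left out, which removed 5635 and left 12559. Among called genes with several probe sets past the same line, all probe sets had 1 sign in 90.8% for CiCM against MEF, 87.2% for CM against MEF and 90.3% for CiCM against CM. A further 3742 probe sets without a single gene lay at or above the line and were not used.

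Differences were tested with limma (version 3.58.1, in R 4.3.3; lmFit and eBayes with a variance trend, 2-sided) in 1 fit of all 9 arrays, without covariates. p-values were adjusted with the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05 and a log2 difference of at least 1. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1, so single genes rest on the model's shared estimate of spread. Gene lists were tested with limma's camera at a preset correlation of 0.01 and again with a correlation estimated per list, adjusted over 33 lists with at least 5 tested genes out of 35 written in advance. Of 774 list entries 58 had no probe set with a single symbol.

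Genes named in the text are 23 genes of heart and fibroblasts and the treatment targets Axin2, Rarb, Cyp26a1 and Nr4a1, whatever their call. To these were added the 6 highest and 6 lowest called genes of each comparison without overlap between arrays, up to 4 called members of each list described, by size of the difference, and the 8 genes with the largest smaller difference outside both ends, in each direction. Other genes were named as further list members after their values were seen, among them Myod1, Myog, Mymk, Ttn, Mybpc3 and Ckm.

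Alternatives were another pseudocount, no filter or a filter at the 75th percentile (8.91), quantile normalization, centring on array medians, the mean over probe sets, only the 2 groups compared, no variance trend, array weights, no minimum difference, the replicate number as a block and leaving out each array in turn. The correlation and covariance of differences that share the MEF arrays were set beside 100 simulated data sets with no effect. The tests were checked on simulated data built from the 12559 genes of the CiCM and MEF comparison with 200 changed genes: 76.3% were recovered at a log2 difference of 1.5 and 85.4% at 2, and 2.77% of calls were false. The cell cycle list, with every gene shifted by 1, passed in 10 of 10 further simulated data sets. In all these data the noise was independent between genes. The list check therefore does not cover lists of correlated genes, such as oxidative phosphorylation with an estimated correlation of 0.77. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.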

Results

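Gene expression was measured in 3 kinds of mouse cells, with 3 arrays of each and 9 arrays in all. Mouse embryonic fibroblasts (MEF), which are connective tissue cells grown from embryos, came from C57BL/6 embryos at embryonic day 13.5. Chemically induced cardiomyocyte-like cells (CiCM) were made from such fibroblasts with a cocktail of 6 small molecules, and clusters that were contracting were picked on day 24. The cocktail held 10 µM CHIR99021, which inhibits the kinase GSK3 and so raises Wnt/beta-catenin signalling. It also held 10 µM RepSox, an inhibitor of the TGF-beta receptor kinase, and 50 µM forskolin, which activates adenylyl cyclase and raises cAMP. Valproic acid at 0.5 mM inhibits histone deacetylases, Parnate at 5 µM inhibits monoamine oxidases and the histone demethylase LSD1, and TTNPB at 1 µM activates retinoic acid receptors. Cardiomyocytes (CM), the contracting cells of the heart, were isolated from mouse hearts. The labels call the 3 samples of a group biological replicates, and the number of arrays limits the precision of every value.

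The design sets the induced cells against the fibroblasts they came from and against the heart cells they were meant to resemble. Values are log2 signals, and a difference of 1 is a doubling. Across the 12559 genes tested, arrays of one group correlated at a mean r of 0.973 in MEF, 0.967 in CiCM and 0.940 in CM. These correlations are across genes, which are not independent replicates. The mean r between groups was 0.769 for MEF and CiCM, 0.677 for CiCM and CM, and 0.591 for MEF and CM. The median SD of a gene over 3 arrays was 0.108 in MEF, 0.164 in CiCM and 0.239 in CM. CM replicate 1 stood apart from the other CM arrays in atrial genes such as Sln, at 14.95 against 8.14 and 2.97, and Myl7, at 15.05 against 9.25 and 5.98.

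**Figure D1:**
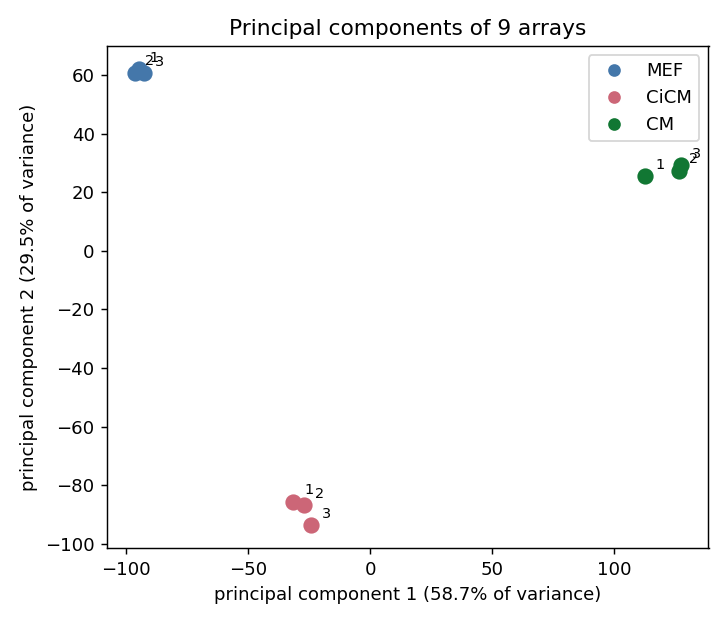
Principal components of the 9 arrays over the 12559 tested genes, with component 1 (58.7% of the variance) on the x axis and component 2 (29.5%) on the y axis, in units of log2 signal summed over genes. Each point is 1 array, coloured by group and numbered by replicate; the 3 groups occupy separate areas of the plot.

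CiCM carried transcripts of striated muscle that were near the floor of the arrays in MEF. All 25 tested genes of the skeletal muscle list were higher in CiCM than in MEF, with a median difference of 9.07 (camera adjusted p = 1.96e-16; adjusted p = 0.00270 with an estimated correlation). The filter on low values shapes that count, since a gene silent in MEF and CM was tested only if CiCM carried it; Pax3, Pax7 and Myf5 of the list were under the filter. Myh8 (Entrez Gene 17885), the perinatal skeletal myosin heavy chain, was at 14.46 ± 0.13 in CiCM and 0.80 ± 0.97 in MEF (log2 signal, SD, n = 3), a difference of 13.66 ± 0.82 (SE, limma adjusted p = 3.92e-07). Myh4 and Myh1, adult fast skeletal myosins, were higher by 12.94 and 11.34, Myl1, a fast skeletal light chain, by 11.19, and Neb, the giant thin-filament protein nebulin, by 11.18. Those MEF values lay far below 6.58, the median of the table, where signals are noisy. With 32 added to each linear signal, the differences of Myh8, Myh4, Myh1, Myl1 and Neb were 9.38, 8.78, 8.65, 9.20 and 7.87. The myogenic regulators Myod1 and Myog were higher by 5.90 and 8.56, and Mymk, which drives myoblast fusion, by 8.05 (4.28, 6.62 and 6.52 with 32 added).

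Sarcomere genes listed for the heart rose as a group. Of 25 tested genes, 21 were higher in CiCM than in MEF, none was lower, and the median difference was 6.80 (camera adjusted p = 8.61e-15; adjusted p = 0.00270 with an estimated correlation). Myom2, an M-band protein of striated muscle, was higher by 11.84, Tnni1, the slow skeletal and fetal heart troponin I, by 10.22, Ttn (titin) by 10.09 and Myoz2, a Z-disc protein, by 9.55. With 32 added the differences of Myom2, Tnni1, Ttn and Myoz2, whose MEF signals lay under 6.58, were 8.01, 8.65, 8.23 and 7.70. Tnnt2, the cardiac troponin T, was at 14.50 ± 0.04 in CiCM and 7.60 ± 0.41 in MEF, and Actc1, the cardiac alpha-actin, at 13.66 ± 0.06 and 7.14 ± 0.10 (SD, n = 3). The limma adjusted p was 1.48e-09 for Tnnt2 and 4.35e-10 for Actc1. Actn2, the sarcomeric alpha-actinin, was higher by 8.54 and Myh7, the slow myosin of ventricle and slow skeletal fibres, by 6.80. Myh6 (Entrez Gene 17888), the heart's alpha-myosin, was at 7.13 ± 0.75 in CiCM and 2.60 ± 2.41 in MEF (SD, n = 3; limma adjusted p = 0.00201), and Tnni3, the cardiac troponin I, was higher by 2.72 (limma adjusted p = 0.00806). The Myh6 call was lost when its probe sets were averaged (1.97), and neither Myh6 nor Tnni3 reached the minimum difference with the largest planned constant added to the signals (0.97 and 0.43). The atrial light chain Myl7 was at 4.66 ± 0.25 in CiCM and 3.66 ± 2.42 in MEF (limma adjusted p = 0.688).

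**Figure D2:**
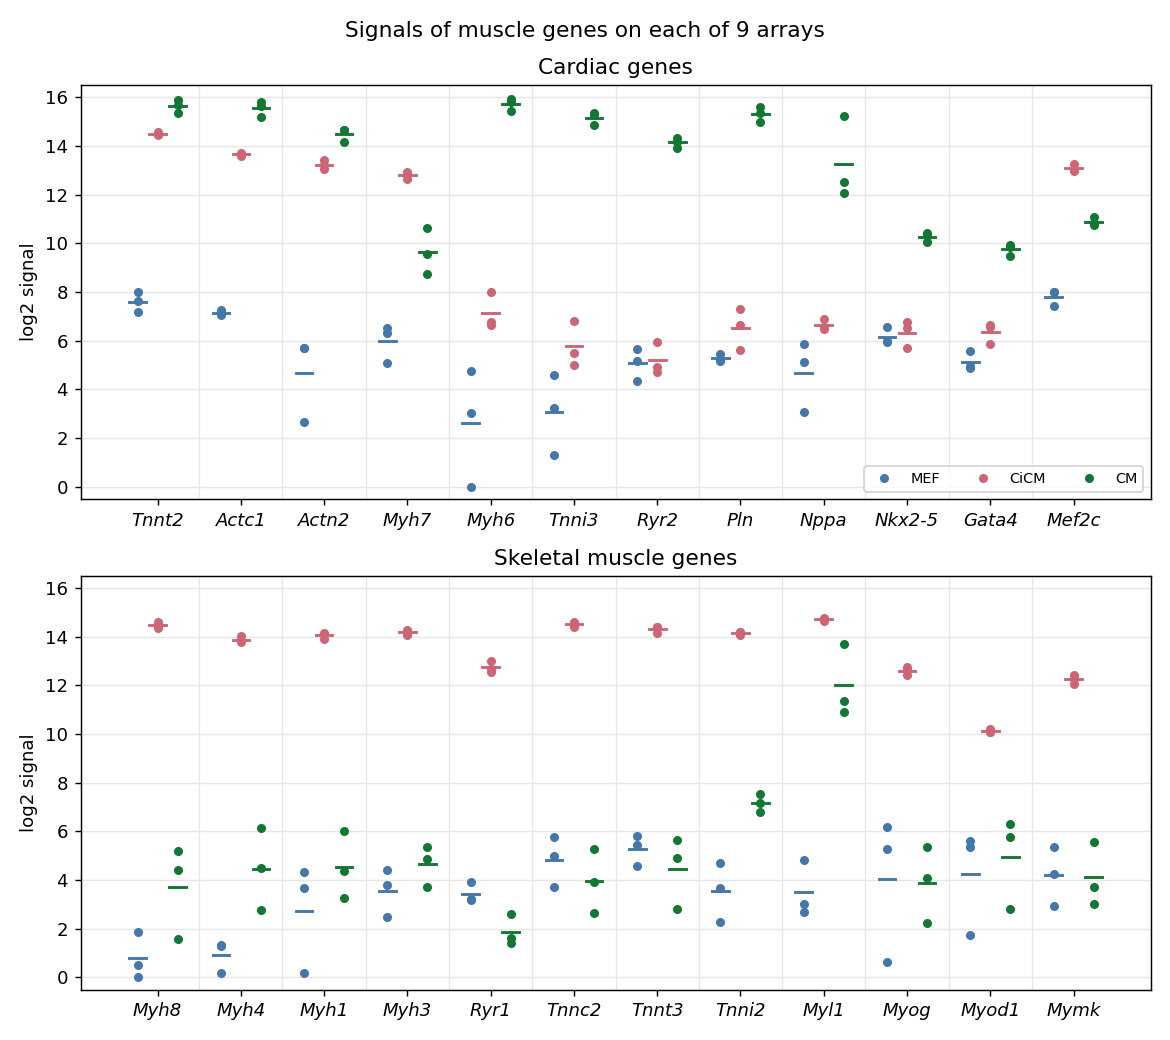
Log2 signal (y axis) of 12 genes listed for the heart (upper panel) and 12 genes listed for skeletal muscle (lower panel) on each of the 9 arrays; points are single arrays and horizontal bars are means of 3 arrays per group. Skeletal muscle genes such as Myh8 sit at 14.46 in CiCM against 0.80 in MEF and 3.73 in CM, while Myh6 sits at 7.13 in CiCM against 15.72 in CM.

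Regulators and membrane proteins of the heart were less uniform. In the list of cardiac transcription factors, 10 of 20 genes were higher in CiCM than in MEF and 2 were lower, with a median of 0.95 (camera adjusted p = 0.0414; adjusted p = 0.234 with an estimated correlation). Smyd1, a muscle histone methyltransferase, was higher by 6.25 (4.98 with 32 added), Mef2c by 5.27 and Tbx3 by 2.30, while Zfpm2, a GATA cofactor, was lower (-3.86). Smyd1 and Mef2c are also expressed in skeletal muscle. Gata4 was at 6.35 ± 0.43 against 5.14 ± 0.36 in MEF (SD, n = 3; limma adjusted p = 0.00686), a call lost with 32 added (0.76) or with probe sets averaged (0.22). Hand2 was lower (-1.25, limma adjusted p = 0.000374), a call lost with 32 added (-0.98), with the largest planned constant (-0.60) and with probe sets averaged (-0.06). Nkx2-5 differed by 0.16 (limma adjusted p = 0.692) and Tbx5 by -0.45 (limma adjusted p = 0.566). Among genes of calcium handling and ion channels, 9 of 22 were higher, none was lower and the median was 0.63 (camera adjusted p = 0.00444; adjusted p = 0.160 with an estimated correlation). Trdn (triadin), Casq2 (calsequestrin), Hrc and the calcium pump gene Atp2a2 were higher by 8.15, 7.72, 6.20 and 3.94, or by 5.51, 6.94, 5.51 and 3.91 with 32 added, since the MEF signals of the first 3 lay under 6.58. Ryr2, the calcium release channel of the heart, was at 5.19 ± 0.65 in CiCM and 5.06 ± 0.66 in MEF (limma adjusted p = 0.794). Since all 25 tested skeletal muscle genes were higher in CiCM too, rises in the heart lists do not by themselves point to heart muscle. In the list of natriuretic peptides and fetal heart genes, 5 of 9 were higher (median 3.25, camera adjusted p = 0.00337; adjusted p = 0.440 with an estimated correlation), namely Tnni1, Myl4 (7.48), Myh7, Acta1 (5.21) and Ankrd1 (1.63). The natriuretic peptide genes Nppa (1.95, limma adjusted p = 0.0708) and Nppb (-0.50, limma adjusted p = 0.359) did not pass the test, although Nppa passed without CM replicate 1 (1.95) or MEF replicate 2 (2.53).

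Some genes of mitochondrial energy supply were called higher in CiCM than in MEF, while most were not called. The quartiles of the differences were 0.71 and 1.01 for oxidative phosphorylation and 0.45 and 0.78 for the citrate cycle. For fatty acid genes they were -0.02 and 1.15. Many uncalled genes thus rose by less than the minimum difference of 1. Oxidative phosphorylation had 12 of 46 genes higher and none lower (median 0.83, camera adjusted p = 9.88e-15; adjusted p = 0.440 with an estimated correlation). Among the higher genes were Cox8b (9.61, or 7.19 with 32 added), Cox6a2 (5.20) and Cox7a1 (4.14), muscle forms of cytochrome oxidase subunits. Fatty acid uptake and oxidation had 8 of 24 genes higher (median 0.74, camera adjusted p = 0.000251; adjusted p = 0.456 with an estimated correlation), among them Fabp3 (5.27), which carries fatty acids in muscle, and Pdk4 (4.15), which restrains pyruvate oxidation. In the citrate cycle, 4 of 18 genes were higher and 1, Idh2 (-1.38), was lower (median 0.61, camera adjusted p = 0.000504; adjusted p = 0.464 with an estimated correlation).

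Proliferation genes were lower in CiCM. In the cell cycle list, 27 of 28 genes were lower than in MEF and none was higher, with a median of -3.66 (camera adjusted p = 1.35e-14; adjusted p = 0.0127 with an estimated correlation). Examples are Kif20a (-5.53), Bub1 (-5.42), Top2a (-5.28) and Cenpa (-5.14), which act in mitosis and chromosome handling. Their CiCM signals lay under 6.58, so their order is uncertain, and with 32 added the differences of Kif20a, Bub1, Top2a and Cenpa were -4.12, -4.29, -4.82 and -4.54. Depdc1a, a gene of dividing cells outside the list, was lower as well (-6.19). Macrophage and immune cell markers, which the MEF arrays carried, were also lower: 21 of 23 genes fell, with a median of -2.55 (camera adjusted p = 6.65e-11; adjusted p = 0.155 with an estimated correlation). They include Aif1 (-5.30), Cd52 (-4.85), the Fc receptor gene Fcgr3 (-4.41) and the integrin gene Itgam (-4.39), at -3.49, -4.26, -3.97 and -3.08 with 32 added. Acod1 (-6.93) and Arg1 (-6.88), enzymes of activated macrophages, were among the 6 lowest genes, with Rtl3 (-7.01), Tll1 (-6.39), a matrix protease, and Cracd (-6.27). CiCM signals of these 6 genes lay under 6.58, and with 32 added the differences of Rtl3, Acod1, Arg1, Tll1, Cracd and Depdc1a were -4.27, -4.09, -5.44, -4.02, -3.81 and -3.42.

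Fibroblast and matrix genes fell in part. Of 22 fibroblast markers, 10 were lower in CiCM and 2 were higher (median -0.93, camera adjusted p = 0.00718; adjusted p = 0.440 with an estimated correlation). Cd44 (-2.13), Snai2 (-1.88) and Thy1 (-1.76) were lower and Lum (lumican) was higher by 2.84. Of 30 collagens and matrix genes, 10 were lower and none was higher (median -0.67, camera adjusted p = 0.00921; adjusted p = 0.440 with an estimated correlation), among them Fmod (-4.05, a call kept in 3 of 9 fits that left out 1 array), Col11a1 (-3.70), Col5a3 (-2.13) and Thbs1 (-2.09). Col1a1 (13.61 ± 0.10 in CiCM, 13.32 ± 0.23 in MEF), Col3a1 (14.82 ± 0.12 and 14.38 ± 0.03), Postn (13.88 ± 0.16 and 14.27 ± 0.08), Fn1 (13.42 ± 0.16 and 14.36 ± 0.01), S100a4 (12.69 ± 0.08 and 12.68 ± 0.04) and Acta2 (14.12 ± 0.12 and 14.79 ± 0.01) differed by less than 1 (SD, n = 3). Fn1 and Acta2 passed the threshold when probe sets were averaged, with differences of -1.51 and -1.60. Vim was lower (-1.07, limma adjusted p = 4.01e-06), a difference of -0.92 with probe sets averaged.

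Targets of several pathways that the cocktail addresses differed between CiCM and MEF, though treatment was not separated from cell type. In the retinoic acid list, 9 of 22 genes were higher and 2 were lower (median 0.66, camera adjusted p = 0.0144; adjusted p = 0.155 with an estimated correlation). Cyp26a1, which degrades retinoic acid, was at 9.96 ± 0.15 in CiCM and 2.09 ± 0.31 in MEF (SD, n = 3; limma adjusted p = 3.58e-06), and the receptor gene Rarb was higher by 4.97, Stra6 by 4.38 (2.57 with 32 added) and Cyp26b1 by 3.73. The Wnt/beta-catenin target Axin2 was higher by 2.15 ± 0.31 (SE, limma adjusted p = 0.000198). Its list split and did not pass (camera adjusted p = 0.362). Of 15 genes 6 were higher, such as Tnfrsf19 (5.72) and Wif1 (3.53), at 4.38 and 2.74 with 32 added. Another 4 were lower, such as Bmp4 (-3.36) and Ccnd1 (-2.55). In the cAMP and CREB list, 7 of 19 genes were higher and 1 was lower (median 0.50, camera adjusted p = 0.0497; adjusted p = 0.440 with an estimated correlation). Fosb (3.40), Nr4a3 (2.41) and Fos (2.09), immediate early genes, led it, while Nr4a1 differed by 0.35 (limma adjusted p = 0.213). In the TGF-beta list, 9 of 19 genes were lower and none was higher (median -0.86, camera adjusted p = 0.00311, or 0.440 with an estimated correlation). Ccn2 (-2.98), Itgb3 (-2.91), Ltbp2 (-2.26) and Ccn1 (-1.64) were among them. Some of these differences were also seen in CM against MEF. Rarb was higher there by 3.54 and Tnfrsf19 by 3.43, and 11 of 19 TGF-beta genes were lower (median -1.86). Cyp26a1 was called higher there too (1.95, limma adjusted p = 0.0193), with a difference of 0.49 with 32 added. Axin2 rose there by 0.96 (limma adjusted p = 0.0164), under the minimum difference. The retinoic acid, Wnt/beta-catenin and cAMP lists did not pass in CM (camera adjusted p = 0.580, 0.299 and 0.946).

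Over all genes, 1451 were higher and 1536 lower in CiCM than in MEF among 12559 tested (limma, adjusted p under 0.05 and a difference of at least 1), and 15 of 33 lists shifted, or 3 with an estimated correlation. Of the 2987 called genes, 2972 had no overlap between the arrays of both groups. Among all tested genes 68.5% had none, and chance gives 10%. Adjusted over the list alone, the counts were equal for every list but the smooth muscle (3 in place of 2 higher), adipocyte (2 in place of 3 higher), pluripotency (0 in place of 1 lower) and inflammatory (14 in place of 13 lower) lists. The share of calls that were higher was 48.6%, against 35.4% with arrays levelled on their hybridisation controls, a scaling that shifted all CiCM minus MEF differences by -0.23. The call for cardiac transcription factors was lost without CiCM replicate 2 or 3 (camera adjusted p = 0.0609 and 0.0538), and that for the cAMP list without MEF replicate 3, CiCM replicate 1, CiCM replicate 2 or CM replicate 2 (camera adjusted p = 0.0752, 0.0803, 0.0504 and 0.0503).

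**Figure D3:**
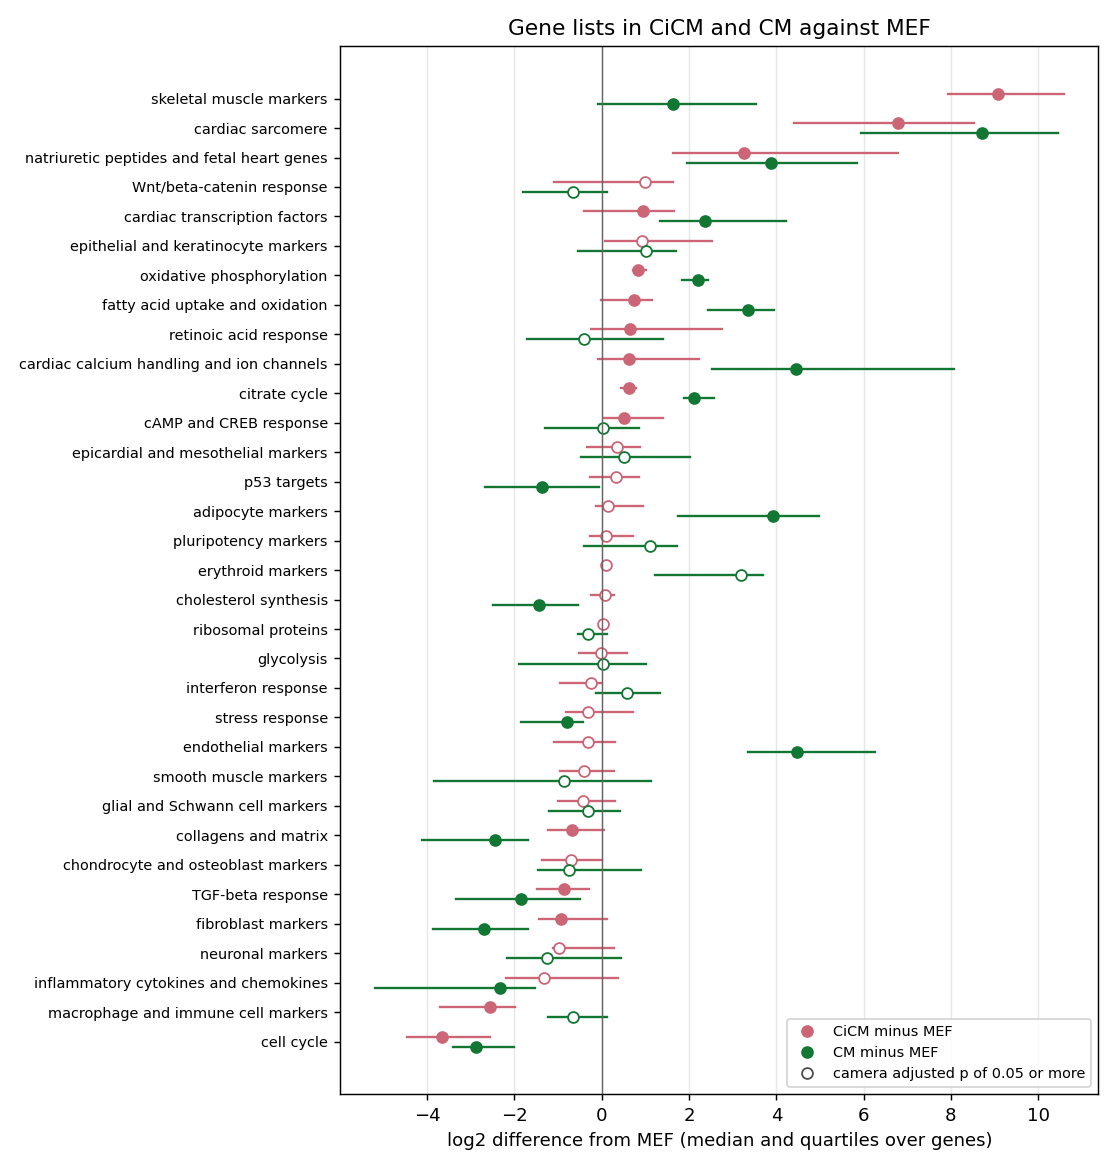
Median log2 difference from MEF (points) with quartiles over the genes of each list (lines) for 33 gene lists, in CiCM and in CM, with open points where the camera adjusted p was 0.05 or more. The skeletal muscle list stands at 9.07 in CiCM and 1.63 in CM, and the list of calcium handling and ion channels at 0.63 in CiCM and 4.46 in CM.

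The comparison of CM with MEF shows what the heart cells carry relative to fibroblasts. Cardiac sarcomere genes were higher in 24 of 25 cases (median 8.71, camera adjusted p = 8.39e-12; adjusted p = 0.00677 with an estimated correlation). Examples are Myom2 (13.47), Myh6 (13.12), Tnni3 (12.10) and Myl3, a ventricular light chain (11.62). Cox8b (11.87) and Ckmt2, the muscle mitochondrial creatine kinase (11.59), were also among the 6 highest. MEF signals of these 6 genes lay under 6.58, so their order is uncertain, and with 32 added the differences of Myom2, Myh6, Tnni3, Myl3, Cox8b and Ckmt2 were 9.63, 10.30, 9.72, 9.94, 9.45 and 9.60. In the calcium handling and ion channel list 18 of 22 genes were higher (median 4.46, adjusted p = 0.0260 with an estimated correlation), among them Pln (phospholamban, 10.03), Trdn (9.77), Ryr2 (9.08) and Kcnip2 (8.80). Their MEF signals lay under 6.58, and with 32 added the differences of Pln, Trdn, Ryr2 and Kcnip2 were 9.17, 7.11, 8.08 and 6.23. Cardiac transcription factors were higher in 16 of 20 cases (median 2.36, adjusted p = 0.0260 with an estimated correlation), with Tbx20 at 8.16, Smyd1 at 7.45, Irx4 at 7.10 and Myocd at 4.99. MEF signals of these 4 lay under 6.58, and with 32 added the differences of Tbx20, Smyd1 and Irx4 were 6.29, 6.18 and 3.74, the last below that of Myocd. Nppa was higher by 8.58 ± 0.83 and Nppb by 5.84 ± 0.43 (SE; limma adjusted p = 4.45e-06 and 5.51e-07), although Nppa varied within CM (SD 1.73, n = 3), where replicate 1 was highest at 15.24. Fatty acid genes (23 of 24 higher, median 3.34), oxidative phosphorylation (45 of 46, median 2.21) and the citrate cycle (18 of 18, median 2.12) were higher too. Their camera adjusted p values were 2.58e-12, 5.44e-18 and 3.42e-10, and with an estimated correlation the adjusted p was 0.189, 0.275 and 0.189.

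Lists of matrix, fibroblast, cell cycle and inflammatory genes were among those that fell in CM. Others were TGF-beta response (11 of 19 lower, camera adjusted p = 0.000810; adjusted p = 0.275 with an estimated correlation), p53 targets (12 of 18, 0.0256; adjusted p = 0.189 with an estimated correlation), stress response (10 of 21, 0.0419; adjusted p = 0.189 with an estimated correlation) and cholesterol synthesis (11 of 18, 0.000531; adjusted p = 0.368 with an estimated correlation). Collagens and matrix genes were lower in 26 of 30 cases (median -2.44, adjusted p = 0.0362 with an estimated correlation), among them Col11a1 (-7.99), Col12a1 (-7.81), Thbs1 (-7.25) and Col1a1 (-4.74). Cell cycle genes were lower in 25 of 28 cases (median -2.88, adjusted p = 0.0362 with an estimated correlation), with Bub1 at -4.19 and Kif20a at -3.87. Fibroblast markers were lower in 19 of 22 cases (median -2.70, camera adjusted p = 1.64e-06; adjusted p = 0.113 with an estimated correlation), with Tnc at -7.75, Lox at -6.78 and Twist2 at -6.37, while Tcf21, a marker of cardiac fibroblasts, was higher by 4.61. The 6 lowest genes were Crabp1 (-11.79), a retinoic acid binding protein, Il6 (-9.46), the serotonin receptor gene Htr1b (-8.56), Arg1 (-8.44), the chemokine gene Cxcl3 (-8.42) and the homeobox gene Hoxc8 (-8.18). Their CM signals lay under 6.58, so their rank is uncertain: with 32 added the differences of Crabp1, Il6, Htr1b, Arg1, Cxcl3 and Hoxc8 were -8.64, -5.67, -6.09, -5.95, -5.95 and -5.20, beside -7.30 for Tnc and -7.19 for Col12a1. Inflammatory cytokines and chemokines were lower in 18 of 22 cases (median -2.33, camera adjusted p = 0.000467; adjusted p = 0.375 with an estimated correlation).

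The CM arrays also carried markers listed for other kinds of cells. Endothelial markers were higher than in MEF in 17 of 18 cases (median 4.48, adjusted p = 0.0260 with an estimated correlation), such as Vwf (9.03), Sox18 (8.20), Cdh5 (6.52) and Tie1 (6.52), or 5.77, 5.84, 5.52 and 4.18 with 32 added. Adipocyte markers were higher in 10 of 16 cases (median 3.93, camera adjusted p = 0.000378; adjusted p = 0.189 with an estimated correlation), with Cidea at 8.88 and Plin4 at 7.08 (5.91 and 5.87 with 32 added). Macrophage and immune cell markers (3 of 23 higher, 7 lower, median -0.67, camera adjusted p = 0.381) and erythroid markers (3 of 5 higher, camera adjusted p = 0.310) did not shift as lists. Their higher members included the antigen presentation genes H2-Aa (9.05) and Cd74 (4.81) and the erythroid gene Alas2 (8.03), at 6.92, 4.38 and 4.82 with 32 added. MEF signals of all 9 of these genes lay under 6.58. The adipocyte list also holds Lpl, a gene of the fatty acid list, so its rise does not by itself show adipocytes. The 3' to 5' difference of the beta-actin control probe sets, which grows as RNA is degraded or copied short, was 1.10 ± 0.21 in CM, 0.36 ± 0.10 in CiCM and 0.25 ± 0.04 in MEF (log2, SD, n = 3). For Gapdh it was -0.25 ± 0.05, -0.37 ± 0.01 and -0.44 ± 0.03. The 18S rRNA control probe sets averaged 13.58 ± 0.19 in CM, 12.81 ± 0.16 in CiCM and 14.26 ± 0.02 in MEF, and the poly-A controls 8.95 ± 0.24, 8.86 ± 0.12 and 8.39 ± 0.06.

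Of the 25 skeletal muscle genes, 11 were higher in CM than in MEF and 2 were lower (median 1.63, camera adjusted p = 0.0459; adjusted p = 0.189 with an estimated correlation). Ckm (9.34), Myl1 (8.48), Neb (4.76) and Tnnt1 (4.41) rose most, by 8.41, 6.51, 1.86 and 3.34 with 32 added, so transcripts of this list were not confined to CiCM. In CM 9 of the 25 genes lay at or above 6.58. Most of these signals were low in both groups, and the median was 0.57 with 32 added, 0.19 with the largest planned constant and 1.00 without the filter. The call was lost without CiCM replicate 1, 2 or 3 (camera adjusted p = 0.0576, 0.0538 and 0.0565). It was also lost with the largest planned constant, without the filter and with the stricter filter (camera adjusted p = 0.0623, 0.0578 and 0.0514). The same held for quantile normalization, only the 2 groups compared, no variance trend and array weights (camera adjusted p = 0.0893, 0.0969, 0.0658 and 0.0692). Altogether 2779 genes were higher and 2736 lower in CM than in MEF (limma), and 18 of 33 lists shifted, or 6 with an estimated correlation. Adjusted over the list alone, the counts changed by 1 gene in the cardiac transcription factor (1 in place of 0 lower) and skeletal muscle (10 in place of 11 higher) lists, and in the epithelial (3 in place of 4 higher, 0 in place of 1 lower) and epicardial (0 in place of 1 lower) lists. The share of higher calls was 50.4% as deposited, 35.1% with arrays centred on their medians and 22.1% with arrays levelled on hybridisation controls, a scaling that shifted all differences by -0.80.

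CiCM and CM carried different muscle genes. Of the 25 skeletal muscle genes, 24 were higher in CiCM than in CM and 1, Ckm (-1.40, a call kept in 5 of 9 fits that left out 1 array), was lower, with a median of 8.07 (camera adjusted p = 1.12e-09; adjusted p = 0.0210 with an estimated correlation). Ryr1 (Entrez Gene 20190), the skeletal calcium release channel, was at 12.74 ± 0.24 in CiCM and 1.88 ± 0.64 in CM (SD, n = 3; limma adjusted p = 2.08e-08). Myh8 was higher by 10.73, Tnnc2, a fast skeletal troponin C, by 10.57 and Tnnt3, a fast skeletal troponin T, by 9.87. Tnni1 (10.87) and Crabp1 (11.07) were also among the 6 highest genes. With 32 added, the differences of Ryr1, Myh8, Tnnc2, Tnnt3, Tnni1 and Crabp1 were 7.58, 8.81, 8.87, 8.46, 8.81 and 7.92.

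Genes typical of heart muscle were lower in CiCM than in CM. Of 25 cardiac sarcomere genes, 13 were lower and 3 were higher (median -1.27, camera adjusted p = 0.000919; adjusted p = 0.0562 with an estimated correlation). Tnni3 (-9.38), Myh6 (-8.58) and Mybpc3, the cardiac myosin binding protein C (-8.26), were far lower, whereas Tnni1, Myl4 (3.60) and Myh7 (3.15) were higher. CM replicate 1 decided the size for Myl4, at 14.92 against 9.67 and 8.36 on the other CM arrays: the difference was 5.57 without it, and the call was kept in 4 of 9 fits that left out 1 array. Tnnt2 (-1.15) and Actc1 (-1.88) were lower by less, and the Tnnt2 call was lost under all 3 other scalings (-0.59, -0.84 and -0.57 with quantile, median and hybridisation-control scaling). Actn2 (-1.27, limma adjusted p = 0.111) and Ttn (-1.03, limma adjusted p = 0.177) did not pass, although Actn2 passed in 4 of the alternatives, such as with 32 added (-1.26). Calcium handling and ion channel genes were lower in 14 of 22 cases and higher in 1 (median -2.44, camera adjusted p = 7.94e-06; adjusted p = 0.0562 with an estimated correlation), among them Kcnip2 (-8.96), a subunit of the transient outward potassium channel, Ryr2 (-8.95), Pln (-8.79) and Kcnj5 (-6.73). With 32 added the differences of Kcnip2, Ryr2, Pln and Kcnj5, whose CiCM signals lay under 6.58, were -6.23, -8.02, -8.32 and -4.83. Cardiac transcription factors were lower in 12 of 20 cases and higher in 3 (median -1.83, camera adjusted p = 0.00348; adjusted p = 0.0808 with an estimated correlation). Tbx20 (-6.45), Irx4 (-6.36), Myocd (-5.37) and Zfpm2 (-4.40) were lower, at -5.61, -3.62, -4.43 and -3.65 with 32 added, since their CiCM signals lay under 6.58. Hand2 (-4.07), Nkx2-5 (-3.94), Gata4 (-3.41) and Tbx5 (-3.38) were lower too, and Mef2c was higher by 2.18. Nppa (-6.63) and Nppb (-6.34) were lower, and Myl7 was lower as well (-5.44, limma adjusted p = 0.0276), a call lost in 6 alternatives, among them without CM replicate 1 (-2.96) and without CiCM replicate 1, 2 or 3 (-5.29, -5.54 and -5.48).

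Energy genes were lower in CiCM than in CM and matrix genes higher. Fatty acid genes were lower in 22 of 24 cases (median -2.44), oxidative phosphorylation in 37 of 46 (median -1.37) and the citrate cycle in 17 of 18 (median -1.63). Their camera adjusted p values were 3.95e-12, 6.86e-15 and 8.81e-10, and with an estimated correlation the adjusted p was 0.117, 0.256 and 0.162. Lpl (-4.56), Cd36 (-4.00), Idh2 (-4.47) and Cox7a1 (-4.20) were among the genes with the largest differences. Adipocyte markers, a list that also holds Lpl, were lower beside them in 12 of 16 cases (median -3.61, camera adjusted p = 0.000152; adjusted p = 0.117 with an estimated correlation), such as Fabp4 (-7.52). Macrophage and immune cell markers were lower in 17 of 23 cases (median -3.14, camera adjusted p = 2.02e-08; adjusted p = 0.110 with an estimated correlation). Collagens and matrix genes were higher in 23 of 30 cases (median 2.02, camera adjusted p = 7.39e-09; adjusted p = 0.0562 with an estimated correlation), such as Col12a1 (7.88), Fbn2 (5.57) and Col1a1 (5.03). Fibroblast markers were higher in 16 of 22 cases (median 1.59, camera adjusted p = 6.99e-07; adjusted p = 0.0878 with an estimated correlation), such as Tnc (6.31) and Twist2 (5.46). Of the fixed fibroblast genes, Col3a1 (1.66), Postn (2.40), Fn1 (2.44), Thy1 (2.44), and S100a4 (3.53) were higher, Acta2 was at 14.12 against 12.62 (a difference of 0.87, under the threshold, with probe sets averaged) and Vim differed by 0.17 (limma adjusted p = 0.122). Endothelial markers were lower in 18 of 18 cases (median -4.82, adjusted p = 0.0210 with an estimated correlation), with Tie1 at -8.58 and Pecam1 at -7.27, and Aplnr, a receptor of vessels, was among the 6 lowest genes (-8.76). With 32 added the differences of Tie1, Pecam1 and Aplnr, whose CiCM signals lay under 6.58, were -4.44, -5.35 and -6.55. Axin2 (1.19), Rarb (1.42), Cyp26a1 (5.92) and Nr4a1 (1.72) were higher. The CM signal of Cyp26a1 lay under 6.58, and its difference was 4.34 with 32 added. The Axin2 difference was 1.01 with probe sets averaged and 0.99 without CM replicate 2, and passed in neither.

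In total 2075 genes were higher and 2387 lower in CiCM than in CM (limma), and 21 of 33 lists shifted, or 2 with an estimated correlation. Adjusted over the list alone, the counts changed by 1 gene in the epithelial (2 in place of 3 lower) and interferon (2 in place of 1 higher) lists. Higher calls made up 46.5% as deposited, 62.4% with arrays centred on their medians and 74.5% with arrays levelled on hybridisation controls, which shifted all differences by 0.58. The medians of all 54 list shifts called in the 3 comparisons kept their sign under quantile, median and hybridisation-control scaling, and 50, 52 and 51 of the calls were kept. Those lost under quantile scaling were cardiac transcription factors and cAMP in CiCM minus MEF, skeletal muscle in CM minus MEF and cell cycle in CiCM minus CM. The p53 and stress calls in CM minus MEF were lost under both other scalings, and the Wnt call in CiCM minus CM with hybridisation controls.

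**Figure D4:**
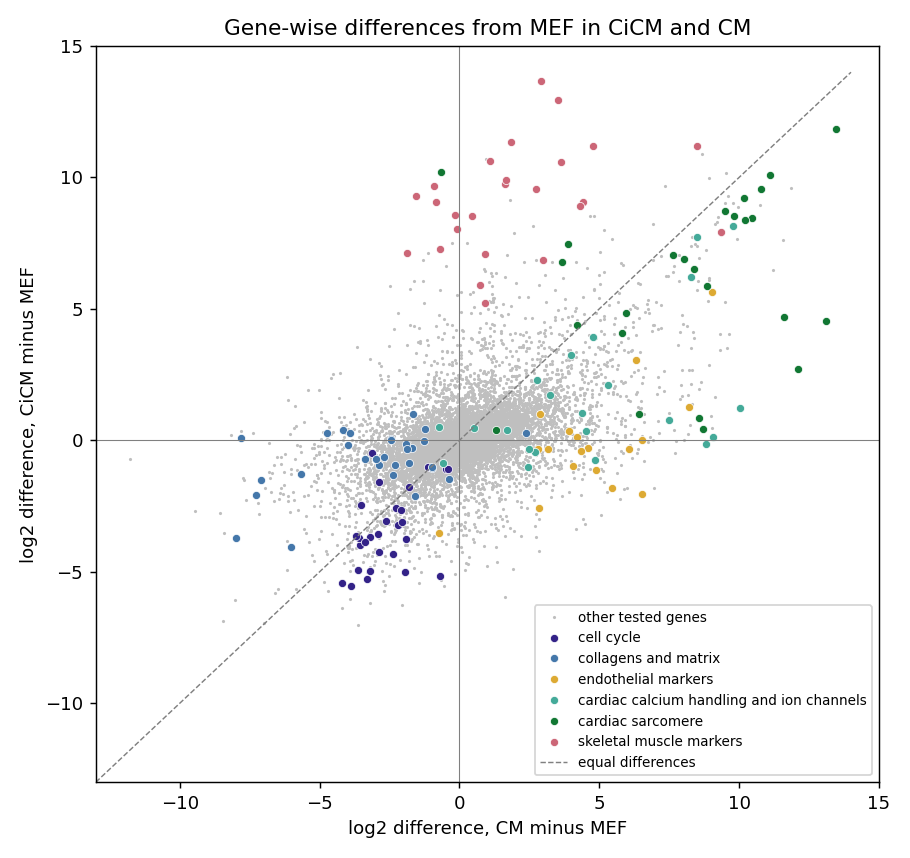
Log2 difference of each tested gene in CM minus MEF (x axis) and in CiCM minus MEF (y axis), with the genes of 6 lists in colour and the dashed line marking equal differences. Of the 25 skeletal muscle genes, 24 lie above the line (list median 9.07 on the y axis and 1.63 on the x axis), and endothelial markers lie to the right of it (median 4.48 on the x axis and -0.33 on the y axis).

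The position of CiCM between the fibroblasts and the heart cells was measured on the genes that separate those ends. Of the 2779 genes higher in CM than in MEF, 905 (32.6%) were also higher in CiCM than in MEF, and of the 2736 lower ones 912 (33.3%) were also lower. Independent lists of these sizes would share 321 and 335 genes, a value that leaves out the shared MEF arrays. Simulated data with no effect against those arrays shared 0.01 genes on average, a value that leaves out the effects and is low because almost no gene is called. Neither is a full no-change value, and the MEF arrays are too few to split, so part of the excess may come from the shared fibroblast arrays. The median CM-high gene had moved 33.7% of the way from MEF to CM on the log2 scale (quartiles 4.90 and 61.7%), and the median MEF-high gene 37.1% (quartiles 10.2 and 68.4%). Per CiCM array, the first median ranged from 31.6% to 36.8% and the second from 35.5% to 38.4%. The CM-high genes are not all genes of heart muscle. They include 17 of 18 endothelial, 10 of 16 adipocyte and 11 of 25 skeletal muscle genes tested. The percent reached is therefore not a share of conversion to heart muscle. The log2 differences from MEF correlated across genes at r = 0.543, beside 0.500 in simulated data with no effect; the covariance was 1.55, beside 0.0554.

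CiCM were also outside both ends for many genes. 497 genes were higher than in both MEF and CM, and 506 were lower than in both. The second count was 175 with the largest planned constant added and 289 with the stricter filter. Both counts rest on the same 3 CiCM arrays in each comparison, which the 240 and 292 genes of independent lists leave out; simulated data with no effect gave 0. The 8 genes with the largest smaller difference were Myh8, Tnni1, Mybph, Tnnc2, Myh3, Myh1, Myh4 and Ryr1, from 9.30 to 10.73; all but Tnni1 and Mybph are in the skeletal muscle list. Their MEF and CM signals lay under 6.58, so their order is uncertain, and with 32 added the smaller differences ran from 7.32 (Ryr1) to 8.81 (Myh8). Genes higher than both ends included 24 of the 25 skeletal muscle genes (adjusted p = 1.01e-31, 2-sided Fisher's exact test over 33 lists, with the 12559 tested genes as background). They also included 6 of 15 Wnt/beta-catenin (0.000227), 6 of 22 retinoic acid (0.00178), 4 of 9 natriuretic and fetal heart (0.00215) and 4 of 19 cAMP genes (0.0386). These values in parentheses are adjusted p of the same Fisher's test. The natriuretic and fetal heart genes among them were Tnni1, Myl4, Myh7 and Acta1, the last also in the skeletal muscle list. Nppa and Nppb were lower in CiCM than in CM (-6.63 and -6.34). The filter admits a gene silent in MEF and CM only when CiCM carried it, so the counts were also taken without it. They were 24 of 28 skeletal muscle, 6 of 20 Wnt, 6 of 24 retinoic acid, 4 of 9 natriuretic and fetal heart and 4 of 21 cAMP genes. Each list passed. Genes lower than both ends included 15 of 23 macrophage markers (adjusted p = 1.17e-14) and 9 of 28 cell cycle genes (adjusted p = 1.50e-05). Fisher's test treats genes as independent, and of the lists named here the skeletal muscle list alone passed camera with an estimated correlation in both comparisons. The 8 with the largest smaller difference were Pcolce2, Klk8, Cmklr1, Meox1, Hspa12b, Cav1, Ebf2 and Hcls1. All but Cav1 lay under 6.58 in CiCM, so their order is uncertain: with 32 added the CiCM minus MEF difference was -4.62 for Cav1, -2.16 for Hspa12b and -1.92 for Hcls1, and the calls of the last 2 against MEF were lost with the largest planned constant. Cav1 (caveolin 1) had the highest signals of these, at 8.21 ± 0.16 in CiCM, 12.98 ± 0.04 in MEF and 13.97 ± 0.20 in CM (SD, n = 3).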

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

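The tests of explanations in this part were chosen after the results were seen, except the counts of other array splits, which were planned. Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real grouping called 2987 genes for CiCM against MEF, 5515 for CM against MEF and 4462 for CiCM against CM, the highest other split called 0 in each, and 1 of 10 splits, the real one, reached the count.

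Several gene groups had medians of opposite sign against MEF in CiCM and CM, with a tested difference between CiCM and CM; none of them passed against MEF in both cell types. Those with both medians more than 0.3 from 0 are given first. The median CiCM minus CM difference was 1.65 for the Wnt/beta-catenin list, 1.71 for the retinoic acid list, -4.82 for the endothelial list and 1.36 for the p53 target list, all past the preset camera test. With an estimated correlation the endothelial list alone passed among these 4. With a smaller median on one side, the cholesterol synthesis (0.08 in CiCM and -1.43 in CM), interferon response (-0.26 and 0.57) and ribosomal protein lists (0.04 and -0.31) passed between CiCM and CM too, though not with an estimated correlation. Single genes called in opposite directions from MEF numbered 79 that were higher in CiCM and lower in CM, and 103 that were lower in CiCM and higher in CM; all 79 and all 103 were also called between CiCM and CM.

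Control probe sets and sex-linked genes, outside the tested lists, showed further differences. The 18 hybridisation controls, added to each sample in the laboratory, were higher in CM than in MEF by 0.80. The control probe set for pyruvate carboxylase was higher in CiCM than in MEF by 2.74, at 10.46 ± 0.20 against 7.72 ± 0.11 (SD, n = 3), and stood at 9.73 ± 1.00 in CM. The 18S rRNA probe sets differed from MEF by -1.44 in CiCM and -0.68 in CM, and the poly-A controls by 0.47 and 0.57. Xist, expressed from the inactive X chromosome of females, differed by 0.84 between CM and MEF (limma adjusted p = 0.424), with 13.65, 13.95 and 9.49 on CM replicates 1, 2 and 3. The Y-linked gene Eif2s3y was at 4.87, 4.67 and 10.94 on the same arrays, while MEF and CiCM arrays carried both Xist and Eif2s3y.

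The skeletal muscle genes of CiCM were weighed against 3 technical explanations. Cross-hybridisation of skeletal probe sets to heart transcripts at least as abundant in CM would have made CM at least as bright. The median of the list in CiCM minus CM was 8.07 (quartiles 5.17 and 9.40). Of its 25 genes, 9 lay at or above 6.58 in CM, and 1 is in another list. Cross-hybridisation to transcripts brighter in CiCM, such as Tnni1 (14.31 against 3.43 in CM), or among skeletal myosin probe sets was not tested. Arrays of skeletal muscle tissue under the CiCM name would bring vessels, but the endothelial list had a median of -0.33 in CiCM minus MEF (quartiles -1.10 and 0.30). Of its 18 genes 3 were lower and 2 were higher, Vwf (5.65) and Sox17 (3.04), at 2.59 and 1.91 with 32 added. A few vessel cells thus stay open. Myoblasts already present among the fibroblasts may be a source and stay open: 0 of Pax7, Myf5 and Myod1 lay above 6.58 on all 3 MEF arrays, which leaves a small share possible, while of all 7 measured progenitor genes 2 did, Six4 (8.51, 8.58 and 8.67) and Met (8.67, 8.55 and 8.67). A myogenic response of fibroblasts to the cocktail was not tested against this.

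The heart genes of CiCM did not move together. If cardiomyocytes with the profile of the CM arrays were the only source, CiCM minus MEF would be about 1 share of CM minus MEF. This would hold for the abundant CM-high genes, on linear signals. Among the 100 most abundant of them the median share of that difference was 25.5% (quartiles 17.2 and 33.3%), yet 11 genes lay under 2.55%, which is 10% of that median. Of these, 6 were bright in MEF, so that a change in other cells could lower their share (Gsn -16.6%), and 5 were under 6.58 in MEF: Mybpc3 (0.0865%), Tnni3 (0.139%), Pln (0.154%), Myh6 (0.262%) and Myl3 (0.807%). The last 5 argue against cells with the profile of the CM arrays as the sole source. Heart muscle cells of another profile, such as fetal ones, were not tested and stay open. Tnni1, the slow skeletal and fetal heart troponin I, was at 14.31 in CiCM and 3.43 in CM, which does not tell these 2 sources apart. Of the 9 natriuretic and fetal heart genes, 5 were higher in CiCM than in MEF. The other 4 were not called, Nppa, Nppb and Myl7 among them. A small share of CM-like cells, and shared sarcomere genes from skeletal-like cells, stay open too.

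CM replicate 1 stood apart in atrial genes, seen first in Myl7, Myl4, Nppa, Sln and Dkk3. The 6 other measured atrial genes (Bmp10, Kcnj3, Kcnj5, Stard10, Tbx5 and Kcna5) had a median of 1.14 in replicate 1 minus the mean of replicates 2 and 3, where the 95th percentile of 10000 random lists of like brightness was 0.32. This is in line with more atrial tissue in that sample. Sex of the animals was argued against by Xist, whose gap from replicate 1 to the nearer CM array was 0.30, while that of replicate 3 was 4.16. Without CM replicate 1, the counts were 1493 higher and 1575 lower in CiCM than in MEF, and 2910 lower in CM than in MEF.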

How the results depend on the processing

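Of 54 list shifts and the genes fixed in advance, highest, lowest or outside both ends, none called in the planned setting changed direction. Counts and shares were stable within 1.5 times or within the spread of the 3 CiCM arrays except as follows; where nothing else is said, the cause was not tested. With the largest planned constant added, 966 genes were higher and 934 lower in CiCM than in MEF and 175 lower than both ends, and the median percent reached was 26.5 (CM-high) and 40.6 (MEF-high); with 32 added it was 29.6 and 39.4. The added constant shrinks differences of dim genes by construction, and signal over background limits such genes. The stricter filter, which tests fewer genes, gave 1001 genes lower in CiCM than in MEF, 289 lower than both, 34.9% for MEF-high genes and r = 0.571. No filter gave r = 0.531. Quantile normalization gave r = 0.530 and 34.9%, median centring 37.1% and 33.1%, and array weights 35.4%, with the lowest weight, 0.306, on CM replicate 1. Levelling on hybridisation controls, chosen after seeing the data, gave 1551 genes higher and 5483 lower in CM than in MEF, 4023 higher and 1377 lower in CiCM than in CM, and 34.1% for MEF-high genes. Without a minimum difference, a looser threshold by construction, the counts were 3043 higher and 3486 lower in CiCM than in MEF, 4218 and 4572 in CM than in MEF, 4077 and 4012 in CiCM than in CM, 1147 and 1195 outside both ends, and 52.6% of MEF-high genes lower in CiCM. With an estimated correlation, 3, 6 and 2 lists passed in place of 15, 18 and 21. Leaving out each array in turn gave 1340 to 1493 genes higher and 1426 to 1575 lower in CiCM than in MEF, 2692 to 2782 and 2651 to 2910 in CM than in MEF, 1947 to 2235 and 2281 to 2391 in CiCM than in CM, and 429 to 532 and 477 to 532 outside both ends. It gave 30.5 to 33.6% and 31.1 to 34.2% of CM-high and MEF-high genes called in the same direction, medians of 32.5 to 35.1% and 34.1 to 38.3%, r of 0.534 to 0.551, and 13 to 16, 17 to 19 and 21 lists. Some differences that were not called changed sign in CiCM minus MEF. In the planned setting they were near 0 for S100a4 (0.01), Ryr2 (0.13) and Nkx2-5 (0.16), but -0.45 for Tbx5 and 1.00 for Myl7. S100a4 changed sign under quantile (-0.0402), median (-0.0477) and control (-0.22) scaling. It also did so without MEF replicate 2 (-0.0154), CiCM replicate 2 (-0.0160) or CiCM replicate 3 (-0.0114), with a leave-one-out maximum of 0.0581. The same held for Nkx2-5 (-0.0714 under control scaling, -0.0666 to 0.48 with arrays left out), Ryr2 (-0.10 under control scaling, -0.23 without MEF replicate 1, -0.24 to 0.43 with arrays left out), Myl7 (-0.34 to 2.01 with arrays left out) and Tbx5 (-1.09 to 0.32 with arrays left out). Among other results of these genes under alternatives, 37 lost and 15 gained a call and 2934 kept their side; of list results 80 lost the call, 43 of them with the estimated correlation, and 1162 kept it. Cyp26a1 in CM minus MEF (1.95) lost its call under 10 alternatives, such as 32 added (0.49), without CiCM replicate 1, 2 or 3 (1.95 each) and without CM replicate 3 (adjusted p 0.0526 to 0.257 over the 10). Deviations of same-numbered arrays from their group means correlated at -0.016 to 0.067 (median -0.0012). For arrays of other numbers the range was -0.044 to 0.029 (median 0.0017). The highest value, 0.067, was that of CiCM replicate 3 and CM replicate 3. With 3 arrays per group these values cannot exclude a pairing of the samples. The replicate block gave 1444 and 1534, 2774 and 2734, and 2063 and 2371 called genes.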

Other observations

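The test of an explanation in this part was chosen after the result was seen. Some lists that were neither muscle nor matrix differed between some of the groups. Cholesterol synthesis genes had none of 18 called between CiCM and MEF (median 0.08), and 11 of 18 were lower in CM than in MEF (median -1.43, camera adjusted p = 0.000531; adjusted p = 0.368 with an estimated correlation), such as Sqle (-4.13) and Cyp51 (-3.80). In CiCM minus CM 14 of 18 were higher (median 1.48, adjusted p = 0.200 with an estimated correlation). Inflammatory genes of MEF split in CiCM: 13 of 22 were lower and 4 were higher than in MEF, without a shift of the list (camera adjusted p = 0.0741). Ccl9 (-4.76) was lower, while the chemokine genes Ccl8 (4.30) and Cxcl5 (2.52) and the acute phase gene Saa3 (1.91, a call kept in 3 of 9 fits that left out 1 array) were higher. Interferon response genes were lower in CiCM than in CM in 8 of 18 cases (median -0.90, camera adjusted p = 0.00529; adjusted p = 0.169 with an estimated correlation), among them Rsad2 (-4.18) and the immunoproteasome genes Psmb9 (-3.32) and Psmb8 (-3.06). Of the p53 targets, 10 of 18 were higher in CiCM than in CM (median 1.36, adjusted p = 0.0892 with an estimated correlation), among them Pmaip1 (7.66, or 6.24 with 32 added) and Eda2r (4.87), and the cell cycle inhibitor gene Cdkn1a was higher in CiCM than in MEF (1.25).

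Some lists showed no shift in either cell type against MEF. Glycolysis had a median of -0.01 in CiCM (3 genes higher, 3 lower of 17) and 0.04 in CM (5 higher, 6 lower), with Pfkm, the muscle phosphofructokinase, higher by 4.04 and 5.16. Neuronal markers (median -0.98 in CiCM and -1.25 in CM), smooth muscle markers (-0.41 and -0.86), glial markers (-0.42 and -0.31), epithelial markers (0.91 and 1.01), pluripotency markers (0.10 and 1.09) and ribosomal protein genes (0.04 and -0.31) did not pass camera's adjusted threshold.

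Hox genes, which mark position along the body, were examined as a hypothesis on origin. Of 24 that passed the filter, 20 were lower in CM than in MEF and none was lower in CiCM than in MEF. In CiCM 2 were higher than in MEF and 23 were higher than in CM (limma). Hoxa2, Hoxa4 and Hoxd13 passed the filter only through their CiCM signals, which shapes their part of the last count. Over those 20 genes the median difference was -3.60 in CM minus MEF and 0.27 in CiCM minus MEF, or -7.52% of the former. Hoxa9 was at 10.26 in MEF, 10.54 in CiCM and 2.88 in CM. The median of these Hox genes in CiCM was thus near that of the fibroblasts. A positional code kept by CiCM would give this, a hypothesis found and tested on the same arrays. Unconverted fibroblasts in the picked clusters, or myoblasts of the same preparation, would give it too, so the values cannot decide between them. Trunk fibroblasts and heart differ in origin. Retinoic acid receptor activation by TTNPB, which can raise some Hox genes, was not separated from a kept code.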
